A study of Mus musculus with 4 samples.

How the data were processed

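Total RNA from sorted Lgr5-high intestinal cells was amplified by a whole-transcriptome method and labelled with a single cyanine dye, per the labels' protocols. Each of the 4 samples was hybridised to its own Agilent mouse array. The deposited scanner tables hold background-corrected spot intensity on a linear scale, made with Agilent Feature Extraction version 12.0.3.1 per the file headers, while the submitters' processing notes name version 11.5.1.1. Flags for outlier, saturated and well-above-background spots were taken as deposited, per the file headers. The deposited series table held each array's intensity multiplied by 1 constant per array, from 5.60 to 6.68, on a linear scale without centring between genes. Its column medians were 249 and 231 in the control and 239 and 223 in the knockout, and the target of that scaling remains unknown. It served as an alternative.

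Each array had 62976 spots, of which 59305 were not controls, carrying 55681 probes. Control spots were left out, and so were spots marked as outliers, of which there were 111 to 172 per array; spots of one probe were averaged. The processed signal was put on the log2 scale and each array's 75th percentile subtracted. A probe was kept when it was well above background on both arrays of at least 1 group, which left 35422 probes. The median coefficient of variation of replicated spots was 9.61% to 12.8% per array, per the file headers, and the mean net signal of negative controls was about 35 on slide 1 (35.3 and 34.8) and about 17 on slide 2 (17.6 and 17.2). The files carry accessions and no gene symbols. Accessions without their versions were matched to the RefSeq gene table of assembly GRCm38.p6, which named 28331 probes (21368 symbols) and left 27350 unnamed here. The array annotation uses build mm9, so no coordinates are given. A gene was represented by its brightest probe over the 4 arrays; named genes with several probes had them on 1 side unless stated. This gave 24866 genes, 14800 with a symbol, and 1 gene with a missing value stayed out of the set tests.

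Groups were compared with limma version 3.58.1 in R version 4.3.3, by a linear fit with moderated variances that follow an intensity trend and Benjamini-Hochberg adjustment at 0.05 over all genes tested. The stated fit has no slide term; the fit with the slide as a block, which is also the replicate number, is given beside it because each slide held both groups. Samples that share a slide deviated together: across genes, control 1 minus control 2 correlated with knockout 1 minus knockout 2 at a Pearson r of 0.563, and the differences within slide 1 and slide 2 at 0.378, with 61.2% of genes on the same side (genes are not independent replicates). The 31 gene lists, the rule for naming genes and the fit without a slide term were set before the data were examined. The rule names Ifnar1, the 8 genes with the smallest unadjusted p in each direction with the same sign on both slides and no clone or locus name (as values, since fewer than 5 passed in the fit without the block), up to 4 members per list by smallest p, and 12 fixed genes of interest. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 31 lists. At the preset correlation 11 lists were called, 13 with the slide block, and 0 with an estimated correlation (smallest adjusted p of 0.277) or with fry (smallest adjusted p of 0.185). Whether the latter tests can call any list with 4 arrays and 2 residual degrees of freedom was not tested.

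The fits were tested on simulated data with 4 arrays and 24865 genes. Without the block, 0% of planted log2 differences of 1 were recovered, 10% at 2, 44% at 3 and 64% at 4, with 0 false calls. With the slide block, 36%, 70%, 88% and 94% were recovered, with 14 false calls. The simulated variances followed the intensity trend fitted with the slide block, so these shares do not test that trend. A planted list was recovered at the preset correlation and 0 of 30 unshifted lists were called. Simulated genes varied independently, so this does not test the preset correlation where members vary together. Estimated correlations in the data ran from -0.106 (fetal and regeneration list) to 0.885 (Paneth list), with 0.618 for interferon-stimulated genes. The median difference over all genes was 0.02 and lay between -0.02 and 0.04 under the other scalings. Alternatives covered the slide block, quantile and median scaling, normexp background correction with an offset of 50, the authors' table, the filter on dim probes, the probe rule, outlier flags, the variance model, the threshold, the set test and leaving out each array. The mean signal column is not used here, so normexp ran on the median signal.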

Results

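Intestinal stem cells were compared between mice that can and mice that cannot respond to type I interferon. The cells were Lgr5-high cells sorted by flow cytometry. Control animals carried the Lgr5 knock-in reporter, and knockout animals carried it on an Ifnar1-deficient background. Ifnar1 encodes a chain of the receptor for interferon alpha and beta. Both groups had received poly(I:C), a synthetic double-stranded RNA that provokes an interferon response, at 2 mg/kg daily for 1 week, so both arms were treated and the comparison is knockout against control under treatment. RNA from 2 samples per group was hybridised to 4 single-colour arrays. The replicate number, the slide and the scan went together, so that slide 1 held control 1 and knockout 1 and slide 2 held control 2 and knockout 2. Between 63.3% and 67.7% of the non-control spots were well above background on each array, and 0 were saturated. The number of arrays limits the precision of what follows. Nothing in the labels says that the samples came from separate animals. The p-values of single genes therefore measure the spread between these samples, which may be technical, with variance partly borrowed from other genes. Camera p-values at the preset correlation compare a list's genes with the other genes. Their small size does not measure agreement between samples.

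Lgr5-high sorts without the receptor held far less interferon-stimulated RNA than control sorts, and they also held less Paneth cell and antimicrobial RNA. The median of the interferon-stimulated list was 3.70-fold lower in the knockout and that of the Paneth cell list 3.73-fold lower. Markers of the stem cell state had a list median of 0.06: Lgr5 itself, the receptor that defines the sorted cells, was at 2.93 ± 0.16 in the control and 3.13 ± 0.28 in the knockout (log2 signal relative to the array's 75th percentile, mean ± SD, n = 2). The sort took Lgr5-high cells in both groups, so a similar Lgr5 level is in part imposed by the sort. Genes higher in the knockout included Chst2, Fstl1 and Xlr3b.

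The targeted gene was examined first. Ifnar1 was at -0.29 ± 0.11 in the control and at -2.02 ± 0.37 in the knockout (log2 signal, mean ± SD, n = 2), which is 3.31-fold lower, with differences of -1.55 on slide 1 and -1.91 on slide 2 (limma with slide block, adjusted p = 0.0496; without the block, adjusted p = 0.478). Its 3 probes lay on the same side. Ifnar1 remained well above background in both knockout samples. The position of its probes relative to the disrupted part of the gene is not given in the sources used here, so the value shows a lower transcript signal under the knockout label and no more.

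Over 24866 genes, the limma fit without a slide term called 0 genes higher and 0 lower in the knockout after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.224. At an unadjusted p under 0.05 it held 258 higher and 427 lower genes. The slides accounted for much of the spread: parting the 4 arrays by slide called 2069 genes and parting them by group 0, each after adjustment. With the slide as a block, that is, a paired comparison of replicate numbers, limma called 8 genes higher and 82 lower, while at an unadjusted p under 0.05 it held 1818 higher and 1226 lower. In what follows a single gene is said to have risen or fallen only where this slide-block fit called it over all genes, or where the adjustment over its list alone is stated. List-alone counts come from the fit without the block unless the slide block is named. The slide-block fit has 1 residual degree of freedom and depends on the intensity trend in the variance. Without the trend, the slide-block fit called 0 genes in either direction (smallest adjusted p of 0.444, with 1036 higher and 1025 lower at an unadjusted p under 0.05). In the fit without the block, leaving out 1 array raised the number of lower genes to 18 without control 1, 71 without control 2, 9 without knockout 1 and 88 without knockout 2, and the number of higher genes to 2 without control 2 and 3 without knockout 2.

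**Figure D1:**
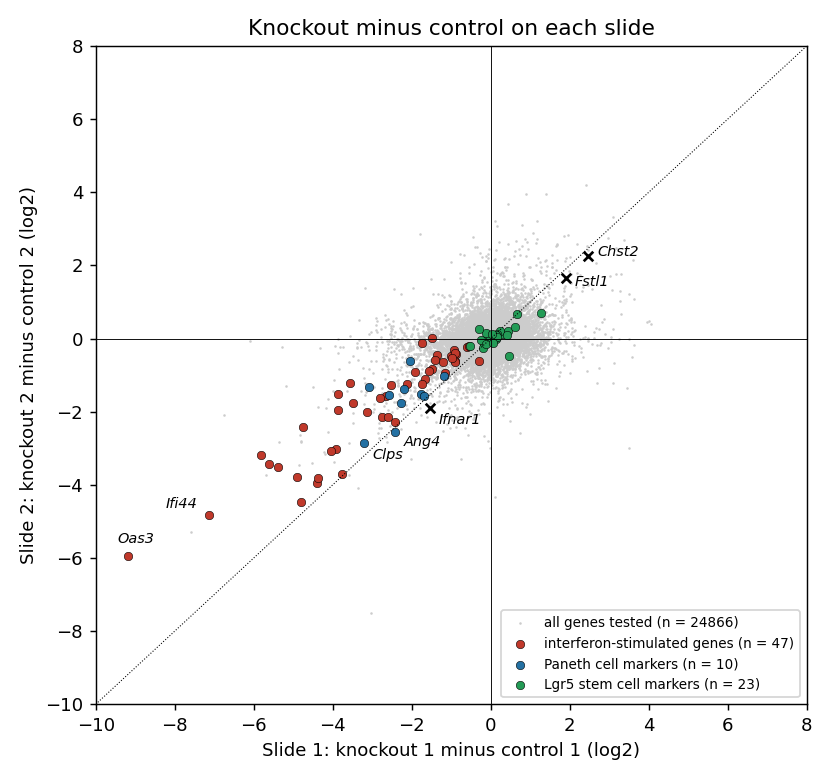
Each point is a gene, placed by its log2 difference, knockout minus control, on slide 1 (horizontal axis) and on slide 2 (vertical axis); grey points are all genes tested, coloured points are members of 3 gene lists, crosses are single named genes and the dotted line marks equal differences. Interferon-stimulated and Paneth cell genes lie at lower left, with list medians of -2.42 and -2.23 on slide 1 and -1.24 and -1.53 on slide 2, while Lgr5 stem cell markers lie near 0.

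Interferon-stimulated genes made up the broadest difference. Of 47 measured members, 46 were lower in the knockout on both slides, and the median difference was -1.89 (log2; -2.42 on slide 1 and -1.24 on slide 2). Adjusted over the list alone, 39 of the 47 fell and 0 rose (42 and 0 with the slide block); over all genes tested, 15 fell with the slide as a block and 0 without it. Irf7, the transcription factor that amplifies interferon production, fell 20.4-fold, from 1.70 ± 0.52 to -2.65 ± 0.27 (mean ± SD, n = 2; limma with slide block, adjusted p = 0.0131). Oas1a, a sensor enzyme that activates RNase L, fell 11.1-fold (adjusted p = 0.0145), and Bst2, the membrane tether that retains budding virus, fell 5.48-fold (adjusted p = 0.0185). Rtp4 fell 21.9-fold and Apol9b, which stands outside the list, 26.1-fold (adjusted p = 0.0335 each). Apol9b differed by -5.68 on slide 1 and -3.73 on slide 2. Xaf1, a promoter of apoptosis, fell 13.3-fold (adjusted p = 0.00665).

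Several interferon-stimulated transcripts were not well above background in the knockout, so that their folds are bounds. For these the control mean was set against the lowest signal well above background on each knockout array, or the probe's own signal where higher. Ifi44 was at least 24.6-fold lower (limma with slide block, adjusted p = 0.0335) and Ifit1, which binds viral RNA lacking a methylated cap, at least 5.53-fold lower (adjusted p = 0.0414). In all, 6 of the 47 members were in this state, and the list median with them at their bounds was -1.89 as well. A median does not move when members stay on the same side of it, so this says little about dim members. With only probes well above background on all 4 arrays, which drops those dim in the knockout, the list median was -1.32. Isg15, a ubiquitin-like modifier and well-known member, did not pass over all genes and differed by -2.39 (-3.56 on slide 1 and -1.23 on slide 2; limma with slide block, adjusted p = 0.236). Camera with a preset correlation called the list lower (adjusted p = 1.4e-77 over 31 lists; 7.67e-49 with the slide block). The call was lost with a correlation estimated from these 4 arrays (adjusted p = 0.277) and with fry (adjusted p = 0.21), and the median was -1.03 with normexp background correction.

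Groups of genes tied to interferon were lower too. Of 14 interferon-inducible GTPases, which attack the vacuoles of intracellular pathogens, 9 fell adjusted over the list alone (9 with the slide block too) and 1 over all genes with the slide block, and the median difference was -1.24 (-1.69 on slide 1 and -0.88 on slide 2; camera adjusted p = 2.29e-18, and adjusted p = 0.277 with an estimated correlation). Igtp fell 4.25-fold (limma with slide block, adjusted p = 0.0335), while Irgm2 differed by -1.29 without passing there. Gbp3 was lower on both slides without passing over all genes, and its signal was well above background on 1 of the 2 knockout arrays, so no exact fold is given. Of 16 genes of MHC class I and antigen processing, 7 fell adjusted over the list alone (9 with the slide block) and 0 over all genes; the median was -0.46 (-0.61 and -0.35 on slides 1 and 2; camera adjusted p = 1.55e-11, and adjusted p = 0.277 with an estimated correlation). Nlrc5, the transactivator of class I genes, differed by -3.34, and the class I heavy chain gene H2-D1 by -1.20, both short of the threshold over all genes with the slide block (limma, adjusted p = 0.0561 each). MHC class II showed no such shift: its 7 genes had a median of -0.11, with -0.61 on slide 1 and 0.32 on slide 2, and camera did not call them (adjusted p = 0.843), except without knockout 2 (median -0.60, adjusted p = 0.0185).

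Among 13 nucleic acid sensors and their adaptors, 2 fell adjusted over the list alone, Irf7 and the helicase Dhx58 (5 members with the slide block), while Irf7 and Eif2ak2 fell over all genes with the slide block, where Dhx58 did not pass (limma, adjusted p = 0.119). Eif2ak2, the kinase that halts translation on double-stranded RNA, was named after its values were seen (difference -1.05; limma with slide block, adjusted p = 0.0345). The sensor list shares 6 of its 13 genes with the interferon-stimulated list, among them every sensor that fell, so its call is not independent of that list; the 7 others had a median of -0.06. The median of all 13 was -0.46 (-0.86 on slide 1 and -0.17 on slide 2; camera adjusted p = 1.6e-07, and adjusted p = 0.277 with an estimated correlation). Ifih1, the sensor of long double-stranded RNA also known as MDA5, differed by -1.42 on slide 1 and -0.59 on slide 2. Ddx58, which encodes RIG-I, differed by -0.91 in group means. Neither passed over all genes, though both were among the 5 that fell over the list alone with the slide block. Of 16 interferon receptor and signalling genes, Ifnar1 was the 1 that fell adjusted over the list alone (3 fell with the slide block), with a list median of -0.22 (-0.28 and -0.16 on slides 1 and 2; camera adjusted p = 0.000119, and adjusted p = 0.277 with an estimated correlation). This list holds Ifnar1 itself, the targeted gene, so its camera call is not independent of the genotype. The list was not tested without Ifnar1. Ifnar2, the partner chain, differed by -0.35. Il10rb, the shared chain of the IL-10 and interferon lambda receptors, was not well above background in the knockout and did not pass over all genes. Its 2.87-fold lower value rests on its own dim knockout signals, so it is an estimate and not a bound. The 13 genes near Ifnar1 on chromosome 16 had a median of 0.06 (-0.02 and 0.03 on slides 1 and 2), a mean of -0.13, and no camera call (adjusted p = 0.461). Il10rb belongs to this list too and was its lowest member, while the highest was at 0.20.

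**Figure D2:**
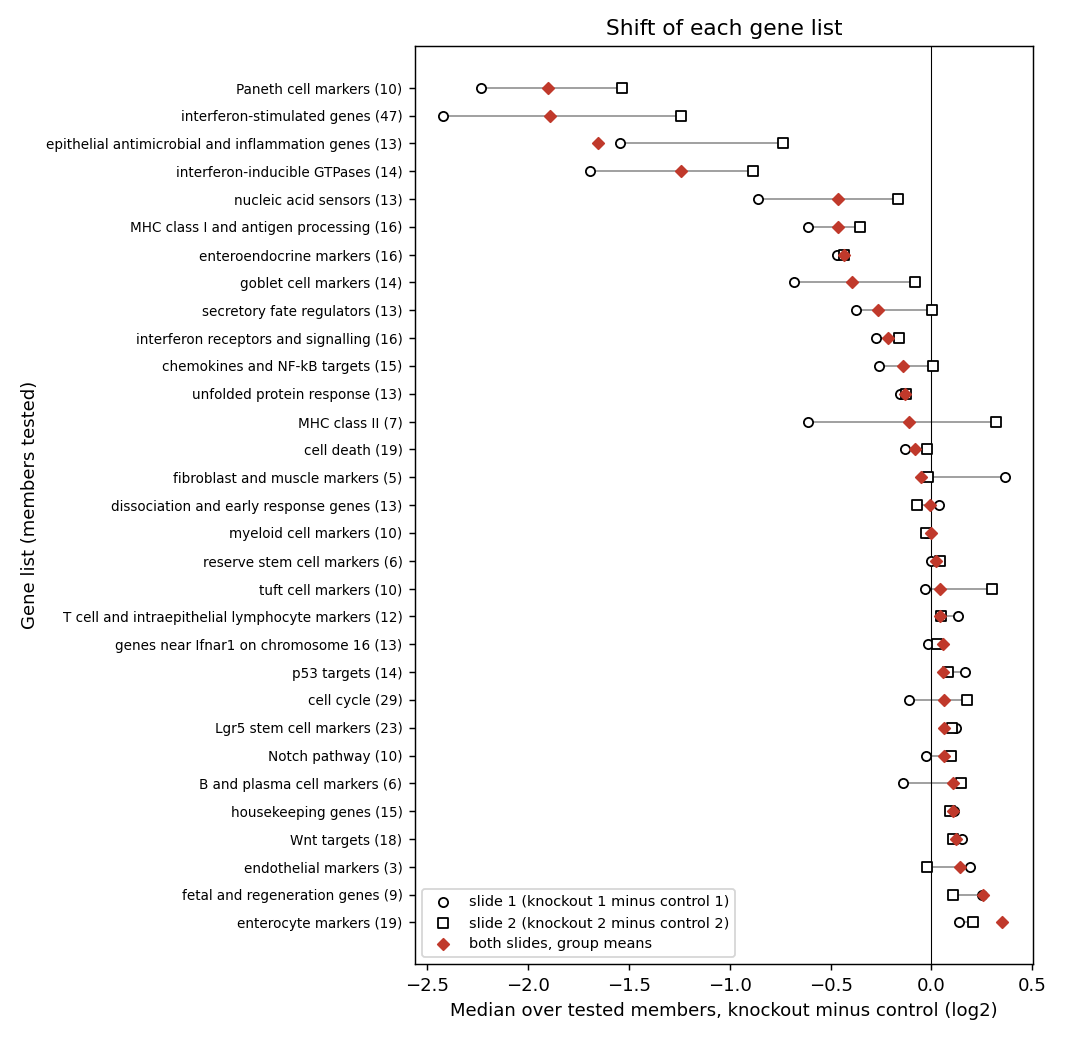
Median log2 difference, knockout minus control, of each gene list over its tested members, whose number stands in brackets; open circles are slide 1, open squares slide 2 and red diamonds the difference of group means. Paneth cell markers (-1.90) and interferon-stimulated genes (-1.89) have the lowest medians and enterocyte markers (0.35) the highest.

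Paneth cell transcripts were lower in the knockout sorts as a group. Paneth cells are the granular antimicrobial cells that sit between Lgr5 stem cells at the crypt base. Of the 17 genes of the list, 7 have no probe named here, and the 10 measured all fell adjusted over the list alone in either fit; 6 of them also fell over all genes with the slide block. The median was -1.90 (-2.23 on slide 1 and -1.53 on slide 2), and the 10 members were lower on both slides. Lyz1, the Paneth cell lysozyme, fell 4.04-fold, from 5.72 ± 0.35 to 3.71 ± 0.71 (mean ± SD, n = 2; limma with slide block, adjusted p = 0.0131). Ang4, an antimicrobial angiogenin, fell 5.64-fold and Clps, a colipase, 8.23-fold (adjusted p = 0.00504 each). Defa3, with 8.12 in the control among the brightest members, fell 3.13-fold (adjusted p = 0.00787), and Defa26 fell 3.45-fold (adjusted p = 0.0496). The 14 alpha-defensin symbols tested were all lower on both slides, 12 of them fell with the slide block, and their folds ran from 2.09 to 4.53; these genes are nearly identical, so one transcript can light the probes of another. Camera called the list (adjusted p = 1.53e-26; adjusted p = 0.277 with an estimated correlation).

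Epithelial antimicrobial and inflammation genes followed the same direction. Of 13 measured, 5 fell adjusted over the list alone (8 with the slide block) and 2 over all genes with the slide block, with a median of -1.65 (-1.54 on slide 1 and -0.74 on slide 2; camera adjusted p = 4.84e-14, and adjusted p = 0.277 with an estimated correlation). That median was -0.78 without knockout 1 and -0.72 with normexp background correction. Reg3b, a secreted lectin, fell 5.61-fold (limma with slide block, adjusted p = 0.0298) and Reg4 fell 6.42-fold (adjusted p = 0.00787). Its relative Reg3g, a lectin active against Gram-positive bacteria, differed by -2.37 (adjusted p = 0.0518), and Duoxa2, the maturation factor of an epithelial oxidase, by -1.65 (adjusted p = 0.0917). Mt2, a metallothionein, fell 4.40-fold, from 6.19 ± 0.04 to 4.06 ± 0.07 (mean ± SD, n = 2; limma with slide block, adjusted p = 0.00504). The chemokine gene Ccl9 fell 4.77-fold (adjusted p = 0.0115).

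Other secretory lineages shifted less. The 14 goblet cell markers had a median of -0.39, which was -0.68 on slide 1 and -0.08 on slide 2. None passed over all genes in either fit, and adjusted over the list alone 0 fell, or 1 with the slide block. Muc2, the main intestinal mucin, differed by -0.88 and Spink4 by -1.55. The 16 enteroendocrine markers had a median of -0.43 (-0.47 and -0.43 on slides 1 and 2), with 0 passing over all genes and 0 over the list alone, but 5 falling over the list alone with the slide block. Chgb differed by -0.81 (limma with slide block, adjusted p = 0.0561), Cpe by -1.17 and Chga by -0.89. Among 13 secretory fate regulators, Atoh1, the master factor of secretory cells, differed by -0.52, and the list median was -0.26 (-0.37 on slide 1 and 0.01 on slide 2), with 0 passing in either fit, over all genes or over the list alone. Camera called the goblet (adjusted p = 0.000251), enteroendocrine (7.66e-05) and regulator lists (0.0132) lower, but with an estimated correlation the adjusted p-values were 0.663, 0.393 and 0.627. The goblet call was also lost without knockout 1 (median -0.15, adjusted p = 0.659), the enteroendocrine call without control 2 (median -0.46, adjusted p = 0.119) and the regulator call without control 1 or knockout 1 (medians -0.19 and -0.07, adjusted p = 0.223 and 0.524).

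**Figure D3:**
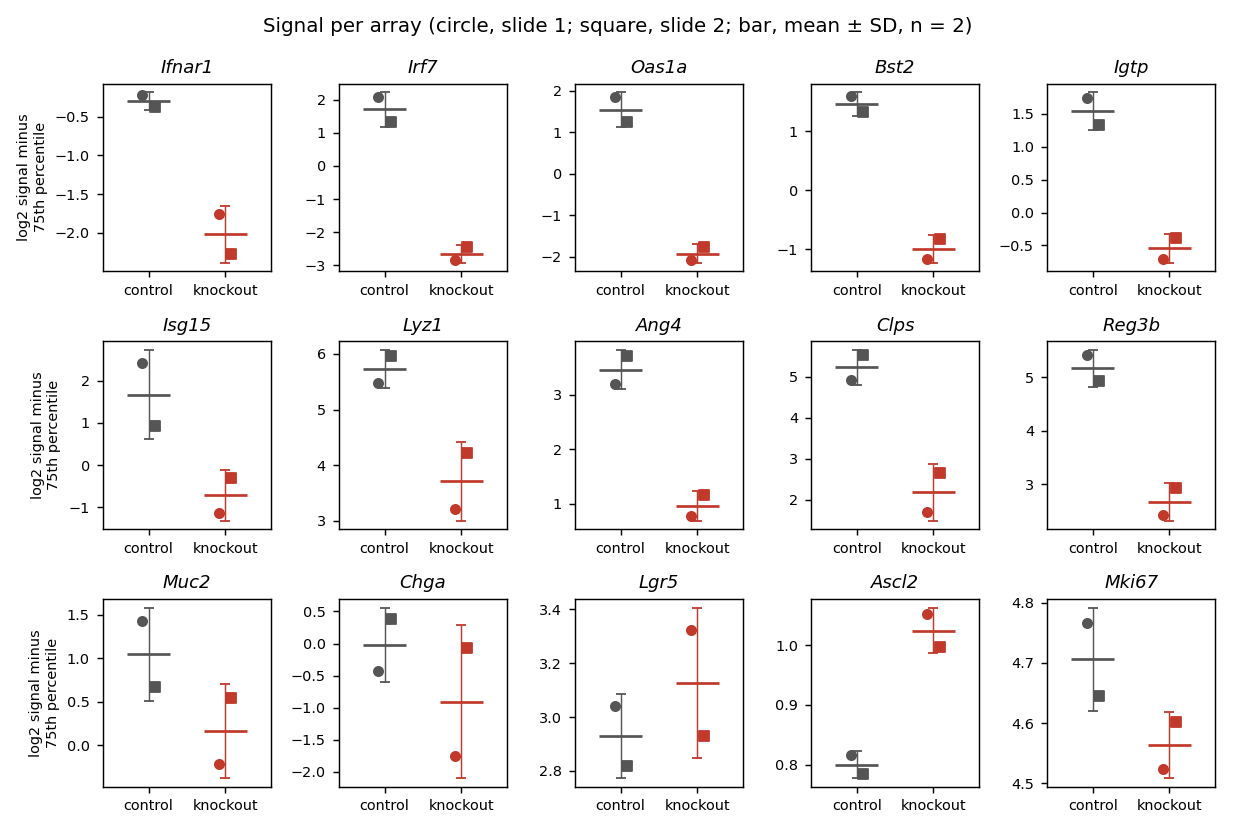
Log2 signal relative to the array's 75th percentile for 15 genes on each of the 4 arrays; circles are slide 1, squares slide 2, and bars the group mean ± SD (n = 2). The vertical axis differs between panels, so that Irf7 spans 1.70 to -2.65 between group means while Lgr5 spans 2.93 to 3.13.

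Stem cell identity and proliferation genes did not pass over all genes in either fit. Of 23 Lgr5 stem cell markers, 0 passed over the list alone, though 2 rose there with the slide block; their median was 0.06 (0.12 on slide 1 and 0.10 on slide 2; camera adjusted p = 0.212, but 0.0485 without knockout 2, where the median was 0.11). Ascl2, a transcription factor of these cells, differed by 0.23, Tnfrsf19 by 0.67 and Slc14a1 by 0.98. Olfm4, a widely used marker, has no probe named here. Among 18 Wnt targets, Lef1, a mediator of Wnt signalling, was the 1 that rose adjusted over the list alone (3 rose with the slide block); it was not well above background in the control and at least 2.24-fold higher in the knockout. The Wnt list median was 0.12 (0.15 and 0.11 on slides 1 and 2; camera adjusted p = 0.0741, but 0.00838 with quantile scaling). The 6 reserve stem cell markers had a median of 0.02 (-0.000408 and 0.04; adjusted p = 0.874) and 10 Notch pathway genes one of 0.06 (-0.03 and 0.10; adjusted p = 0.982). The 29 cell cycle genes had a median of 0.06 (-0.11 on slide 1 and 0.18 on slide 2; adjusted p = 0.403, but 0.0169 without control 1, where the median was 0.17), and 2 of them rose over the list alone with the slide block (0 without), with Mki67, the proliferation antigen, at -0.14 and Mcm6, a subunit of the replicative helicase, at 0.45.

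Death and stress groups were mixed. Of 19 cell death genes, 2 of which are also in the interferon-stimulated list, Xaf1 was the 1 that fell adjusted over the list alone in either fit, and Mlkl, the effector of necroptosis, differed by -0.76. Their median was -0.08 (-0.13 on slide 1 and -0.02 on slide 2), and camera called the list lower (adjusted p = 0.00643), which was lost with an estimated correlation (adjusted p = 0.393) and without knockout 1 (median 0.03, adjusted p = 0.145). The 14 p53 targets had a median of 0.06 (0.17 and 0.08; camera adjusted p = 0.585) and 13 unfolded protein response genes one of -0.13 (-0.15 and -0.13; adjusted p = 0.186, and 0.037 with the slide block). The 13 dissociation and early response genes had a median of -0.01 (0.04 and -0.07), a mean of 0.09 and an adjusted p of 0.585, with the heat shock gene Hspa1a at 0.92. The 15 chemokines and NF-kB targets had a median of -0.14 (-0.26 and 0.01; adjusted p = 0.0702), with Tnf at -1.52; camera called this list without control 1 (median -0.31, adjusted p = 0.0154) and without knockout 2 (median -0.37, adjusted p = 0.00527). Over the list alone with the slide block, 2 dissociation genes rose and 1 chemokine list gene fell, against 0 in each without it. In the fetal and regeneration list, Ly6a, the surface marker Sca-1 and itself inducible by interferon, fell 17.9-fold (limma with slide block, adjusted p = 0.0235). Its control samples lay apart (0.87 ± 1.90, mean ± SD, n = 2), and it differed by -4.86 on slide 1 and -3.47 on slide 2. The 9 genes of that list had a median of 0.25 (0.25 and 0.11), a mean of -0.21 and a camera adjusted p of 0.6.

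Markers of other cell types that the sort could hold went different ways. The 19 enterocyte markers had a median of 0.35 (0.13 on slide 1 and 0.21 on slide 2) and a mean of 0.22. That median was 0.14 without control 2 and 0.0948 with normexp. Camera did not call the list (adjusted p = 0.0508), but did without control 1 (median 0.26, adjusted p = 0.0407) and with quantile scaling (adjusted p = 0.0459), probe means or all probes. Among its members were Alpi, the brush border alkaline phosphatase, at 1.14, Fabp2 at 0.49 and Anpep at -0.90. The 10 tuft cell markers had a median of 0.04 (-0.03 and 0.30; adjusted p = 0.585), 12 T cell and intraepithelial lymphocyte markers one of 0.04 (0.13 and 0.05; adjusted p = 0.461) and 6 B and plasma cell markers one of 0.11 (-0.14 and 0.15; adjusted p = 0.874), with a mean of -0.12 in the last. Among 10 myeloid markers, Lyz2, the second lysozyme gene and close in sequence to Lyz1, fell 6.24-fold (limma with slide block, adjusted p = 0.00828), and the list median was -0.00101 (-0.03 and -0.03), with a mean of -0.32 (camera adjusted p = 0.21). The 5 measured fibroblast and muscle markers had a median of -0.05 (0.36 and -0.02), a mean of 0.20 and an adjusted p of 0.584, and 3 endothelial markers a median of 0.14 (0.19 and -0.02; adjusted p = 0.585). The 15 housekeeping genes had a median of 0.11 (0.11 and 0.09; adjusted p = 0.149, and 0.0189 with the slide block), with Tfrc, the transferrin receptor, at 0.48. None of the named genes in these lists other than Lyz2 passed over all genes. Adjusted over the list alone with the slide block, 3 enterocyte markers rose and 1 fell, 2 housekeeping genes rose and 1 T cell marker rose, against 0 in each without the block.

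The slide-block fit called 8 genes higher in the knockout. Chst2, a carbohydrate sulfotransferase, rose 5.13-fold, from -2.04 ± 0.28 to 0.32 ± 0.13 (mean ± SD, n = 2; limma with slide block, adjusted p = 0.0145). Fstl1, a secreted follistatin-like protein, rose 3.42-fold (adjusted p = 0.0131) and Xlr3b, an X-linked lymphocyte-regulated gene, 2.98-fold (adjusted p = 0.0342). Cyp2e1, a cytochrome P450, rose 2.36-fold (adjusted p = 0.0349) and Fabp5, a fatty acid binding protein, 2.14-fold (adjusted p = 0.0423). Xlr4a differed by 2.13 without passing (adjusted p = 0.069). Car2, a carbonic anhydrase, was higher on both slides without passing (adjusted p = 0.0735), and its signal was well above background on 1 of the 2 control arrays, so no exact fold is given. Xlr4b was not well above background in the control and at least 5.71-fold higher in the knockout, also without passing (limma with slide block, adjusted p = 0.116).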

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

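The fit without a slide term called 0 genes higher and 0 lower, and with 4 arrays a random slide block (duplicateCorrelation) could give no correlation and was not run. The replicate block, which is also the slide, gave 8 higher and 82 lower genes and changed the camera call of 2 lists, unfolded protein response and housekeeping genes; it left every list median as it was. An unadjusted p under 0.01 gave 52 higher and 180 lower. The other planned settings gave 0 in both directions. Leaving out an array gave 0 to 3 higher and 9 to 88 lower genes, where the lone sample of a group is assumed to vary like the other group; the block fit has no degree of freedom left then. Combinations with the replicate block were chosen after seeing the data: it gave 34 higher and 147 lower with quantile scaling, 123 and 219 with normexp, 8 and 70 with probes well above background on all 4 arrays, 340 and 426 with no filter, 7 and 82 with a log2 difference of at least 1, and 0 and 0 without the intensity trend. The cause of these differences was not tested. The shift of the interferon-stimulated list kept its direction everywhere, from -2.37 without control 2 to -1.03 with normexp, and -1.41 without control 1 was the smallest with an array left out. Its value of -1.89 was not called by camera with an estimated correlation (adjusted p = 0.277) or by fry (0.21). The estimated correlation between its genes was 0.618 against the preset 0.01. That value does not account for every lost call: the interferon receptor and sensor lists, at -0.06 and 0.0147, lost theirs too. With an estimated correlation, camera has only the 2 residual degrees of freedom of the fit, while the preset form draws on the number of genes. The interferon receptor list at -0.06 and the Paneth list at 0.885 shared an adjusted p of 0.277. A lost call there is therefore weak evidence about a list. The mean over interferon-stimulated members was -2.24. Signal over background limits dim genes: 6 interferon-stimulated members had only bounds in the knockout.

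Lists whose medians lay near 0 changed sign in places, and the cause was not tested. Reserve stem cell markers were at -0.00101 with quantile scaling, -0.0098 with normexp and -0.0177 in the authors' table. Dissociation genes were at 0.0066 with median centring and 0.00103 with normexp. Myeloid markers were at 0.04997 with quantile scaling, 0.012 with median centring, 0.0419 with probe means and 0.0124 over all probes. Genes near Ifnar1 were at -0.00338 with probe means, and tuft cell markers at -0.0101 over all probes. With each array left out, medians ran from -0.00966 to 0.16 for p53 targets, -0.12 to 0.0615 for dissociation genes, -0.10 to 0.0236 for myeloid, -0.0597 to 0.40 for endothelial, -0.043 to 0.0826 for genes near Ifnar1, -0.0158 to 0.28 for housekeeping, -0.60 to 0.42 for MHC class II, -0.0506 to 0.0748 for reserve stem cell, -0.11 to 0.0534 for Notch, -0.00163 to 0.17 for cell cycle, -0.37 to 0.23 for chemokine, -0.0147 to 0.31 for fetal, -0.23 to 0.42 for B cell, -0.22 to 0.19 for fibroblast, -0.25 to 0.0263 for cell death, -0.28 to 0.0396 for unfolded protein response and -0.16 to 0.18 for tuft cell lists. Among lists not called in the stated fit, camera called Wnt targets with quantile scaling (adjusted p = 0.00838), normexp (0.00336), no filter (0.0417), probe means (0.0388) and all probes (0.024), at medians from 0.10 to 0.12. Enterocyte markers were called with quantile scaling (0.0459), probe means (0.0377) and all probes (0.028), unfolded protein response with quantile scaling (0.0459), chemokines with probe means (0.0324) and housekeeping genes with all probes (0.0212). Over the alternatives and each array left out, called lists had medians from -2.36 to -1.38 (Paneth), -1.74 to -0.72 (antimicrobial), -1.49 to -0.86 (GTPases), -0.67 to -0.37 (MHC class I), -0.68 to -0.32 (sensors), -0.32 to -0.15 (interferon receptors), -0.72 to -0.15 (goblet), -0.56 to -0.15 (enteroendocrine) and -0.43 to -0.0694 (secretory regulators). No gene named in the text changed sign under any setting.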

Other observations

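All tests in this part were chosen after the values had been seen. Genes of sterol synthesis were higher in the knockout by a small amount on both slides. Of 24 genes of the pathway, 17 were higher on both slides and 1 lower on both, and the median was 0.39 (log2; 0.32 on slide 1 and 0.41 on slide 2), a 1.31-fold difference. Hmgcs1, which commits carbon to the pathway, differed by 0.56, and Msmo1, a sterol demethylase, by 0.62. Sqle, the squalene epoxidase, differed by 0.65 and Idi1 by 0.52. None of these named sterol genes passed over all genes with the slide block. Scd2, a fatty acid desaturase, rose 3.36-fold (limma with slide block, adjusted p = 0.0245). Outside the fixed lists, Mptx1, a mucosal pentraxin gene, fell 13.2-fold (limma with slide block, adjusted p = 0.00898), with differences of -3.36 on slide 1 and -4.08 on slide 2. Within the Paneth list Itln1, an intelectin, fell 3.09-fold (adjusted p = 0.00665).

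Whether sterol synthesis differs as a set stays open. Without the genes that had been noticed first, the other 21 had a median of 0.34, and camera called them at the preset correlation (adjusted p = 0.000319) but not with an estimated one (adjusted p = 0.108). A single array is argued against, since the lowest median with each array left out was 0.23. Over 5 scalings and background corrections the median lay between 0.20 and 0.36. A wider change of lipid synthesis may also be present and stays open: camera gave the 13 fatty acid genes an adjusted p of 0.0671, and 0.202 without Scd2, where 6 were higher and 3 lower on both slides. No biological cause was tested.

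The Paneth cell signal may come from the sorted stem cells or from Paneth cells caught with them in the sort, which was meant to take Lgr5-high cells. A lower share of stem cells in the control, with every other cell type raised alike there, is argued against by enterocyte markers. Their median lay 2.25 above the Paneth median on the log2 scale, more than the summed spread of 1.03. This does not cover a lower share made up by Paneth or other secretory cells. Goblet and enteroendocrine medians were -0.39 and -0.43, while the tuft cell median was 0.04. Signal shared among defensins and lysozymes is argued against by Clps, Mmp7, Habp2 and Nupr1, which belong to neither family and had a median of -2.14, the highest at -1.10. Carry-over of Paneth cells in the control sorts cannot be told apart from lower Paneth gene expression: folds ran from 2.14 to 8.23, and their spread was 3.98 times a member's standard error, but members that other cells also express at some level would fall unequally under carry-over too. The list shares 0 genes with the other lists, and the genotype stays an open, untested explanation.

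The interferon-stimulated difference was smaller on slide 2 than on slide 1, with a ratio of the list medians of 0.512, against 0.686 for Paneth markers. Compressed signal on slide 2 is argued against, since the standard deviation of log2 signals on slide 2 was 1.01 times that on slide 1. The list was lower in control 2 than in control 1 by a median of -0.79, where all genes had a median of 0.10, and in knockout 2 against knockout 1 it was at 0.22, where all genes were at 0.10. A weaker interferon response in the second control sample is a candidate explanation that cannot be told apart from handling of that sample, since it is 1 sample. A smaller median shift on slide 2 was not particular to interferon genes, since every list called lower at the preset correlation had it. Medians on slides 1 and 2 were -1.54 and -0.74 (antimicrobial), -0.68 and -0.08 (goblet) and -0.47 and -0.43 (enteroendocrine). Whether these lists share a cause was not tested.

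Retnlb, a goblet cell effector gene, was at 5.16 in control 2 and well below that on the other 3 arrays (group means of 2.01 ± 4.46 and -3.27 ± 1.29, SD, n = 2). Its difference was -8.42 without control 1 and -2.12 without control 2, and it did not pass over all genes (limma with slide block, adjusted p = 0.177).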
